A study of Homo sapiens with 18 samples.

How the data were processed

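Hep3B cells, a human hepatocellular carcinoma line, were profiled on 18 oligonucleotide arrays in 9 groups of 2. The groups were untreated controls, cobalt chloride (100 µM), deferoxamine (100 µM) and hypoxia (1% oxygen) at 2 h and at 24 h, and nickel chloride (100 µM) at 24 h. Cobalt and nickel ions and deferoxamine, an iron chelator, are widely used as chemical mimics of hypoxia. The labels describe the nickel arrays in other words than the rest and do not say whether they were grown and hybridized with the other 24 h arrays. The labels also give replicate numbers but do not say whether replicates were separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

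The deposited values are signal intensities on a linear scale, 1 per probe set and array. The background subtraction, normalization and probe summary that the authors used are not given in the sources used here. The table held 12626 probe sets. The 67 control probe sets were left out of all tests, which left 12559. Of these, 10943 carried 1 gene symbol, 546 carried several and 1070 carried none. Entrez identifiers of 10934 probe sets matched the reference gene table, which was used for names only, and 0 symbols needed updating. For gene-level statements each of 8225 genes was represented by its probe set with the highest mean over the 18 arrays.

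The table mixed 2 scales that had been made separately. The first scale held the 8 arrays from 2 h and replicate 1 of hypoxia at 24 h. On it the means trimmed by 2% at each end lay between 200.094 and 200.114 and the array medians between 59.2 and 74. The second scale held the other 9 arrays from 24 h, with trimmed means of 1136 to 1224, medians of 95.05 to 108.1 and a lowest value of 1.6 on every array. On 19 control probe sets for background, the array medians were 5.7 to 22.4 on the first scale and 22 to 25.6 on the second. For arrays, their number limits the precision.

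Because of the mixture, the planned single model of all 18 arrays was replaced by a fit for each time point within 1 scale, which had been planned as an alternative. The 2 h fit used 8 arrays in 4 groups. The 24 h fit used 9 arrays in 5 groups, with replicate 2 as the only hypoxia array, so its hypoxia comparisons assumed that hypoxia samples vary as the other groups do. Each fit had 4 residual degrees of freedom. Replicate 1 of hypoxia at 24 h entered neither fit. It was used in the all-array alternative and in checks in the closing sections. Fold sizes at 2 h and at 24 h are on different scales, and no main model was fitted across them. The planned models of interactions of treatment with time and the comparison of controls at 24 h with controls at 2 h were therefore not run.

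Signals were analysed as log2(signal + 16). Within each fit, probe sets with a mean above the 40th percentile were tested, which gave 7535 probe sets per fit and a signal of 35.36 at the filter at 2 h and 55.56 at 24 h. Linear models were fitted with limma 3.58.1 in R 4.3.3, with moderated variances that followed a trend with the mean level. The median prior degrees of freedom were 4.966 at 2 h and 5.579 at 24 h. Probability values were adjusted by the Benjamini-Hochberg method within each comparison, and an adjusted p under 0.05 was required. Log2 fold changes are given ± standard error (SE). With at most 2 arrays per group, SE came from the moderated variance pooled over the groups of a fit.

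Each treatment was compared with the control of its time point, which gave 7 comparisons. Treatments of the same time point were also compared with one another in 8 further comparisons, of which 5 (cobalt against deferoxamine at both times, cobalt and deferoxamine against hypoxia at 2 h, and nickel against cobalt) were added after seeing the data. Changes at 2 h and 24 h were compared by counts of probe sets that passed the test in the same or in opposite directions and by correlations of effects across probe sets. For probe sets that passed in opposite directions, the difference of the effects of the separate fits was also tested, but the selection of these probe sets fixed its outcome and nothing rests on it.

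Genes were named by a rule set before the data were examined. Among genes whose representative probe set passed the test and whose treated arrays lay on the same side of every reference array, those with the largest fold changes were taken, up to 12 in each direction for hypoxia at 24 h, 10 for the other treatments at 24 h and 6 elsewhere. Up to 4 members with the smallest p per list and 19 genes chosen for the treatment were added. Of these 19, 17 had a probe set on the array, while CA9 and EGLN3 had none. The Results print only a part of the genes taken by the rule and leave out some of the largest changes. Examples are ARR3 (1.61 ± 0.33) for hypoxia at 2 h and HOXD1 (−3.71 ± 0.18) for deferoxamine at 24 h. Counts of named genes in the closing section cover all genes taken. There were 22 fixed gene lists. They covered glycolysis, other targets of hypoxia-inducible factor (HIF), iron handling, iron- and 2-oxoglutarate-dependent dioxygenases, metallothioneins and zinc export, oxidative stress, the integrated stress response, heat shock, p53 targets, immediate early genes, inflammatory genes, cell cycle, ribosome biogenesis, cytosolic ribosomal proteins, oxidative phosphorylation, fatty acid oxidation, cholesterol synthesis, and hepatocyte secreted proteins. The rest were markers of fibroblasts, leukocytes, endothelial cells and erythroid cells. Of the genes fixed for each list, 8 HIF targets and 8 dioxygenases also stood in another list, the most for any list. The HIF target and dioxygenase lists share members, and no list test left these out. A shift of dioxygenases is therefore not separate from a shift of HIF targets.

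Lists with at least 3 tested members were tested with camera of limma against all other genes, with a preset correlation of 0.01 between genes and adjustment over lists within a comparison. As alternatives, camera was run with a correlation estimated for each list and fry was run, which tests a list against no change rather than against other genes. Counts of list members that passed are given with adjustment over all probe sets and, where the words over the list alone follow, with adjustment within the list. Other alternatives were quantile normalization, an offset of 64, no level filter, a filter at the 60th percentile and moderated variances without trend. The mean over a gene's probe sets, replicate number as a block and leaving out each compared array in turn were also used. The only hypoxia array of the 24 h fit was not left out. The all-array model, first planned as the main fit, was kept as an alternative. A fit without the nickel arrays and list tests under quantile normalization were added after seeing the data. The closing section gives their effects.

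The fits were tested on simulated data of 7535 probe sets with 200 planted changes, 50 at each of 4 fold sizes. For cobalt at 2 h the recovered share was 34% at 1.5-fold, 72% at 2-fold and 98% at 4-fold, with 10 false among 162 calls. For cobalt at 24 h, 80%, 98% and 100% were recovered, with 7 false among 196 calls. With 1 array against 2, as for hypoxia at 24 h, 60%, 98% and 100% were recovered, with 6 false among 185 calls. All simulated arrays had the same noise for a probe set, independent between arrays. A lone hypoxia array that varied more than the other groups was therefore not tested, and the false calls do not cover that case. A planted list was found in all 3 designs and 0 of 21 unchanged lists were called in each. The simulated genes were independent, so false list calls among correlated genes were not tested. For correlations between effects, which share control arrays, 100 simulations of unchanged groups gave the value expected without any effect. Their noise was independent between probe sets and between arrays. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3.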

Results

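Hep3B hepatoma cells were exposed to 1% oxygen, cobalt chloride or deferoxamine for 2 h or 24 h, or to nickel chloride for 24 h, with 2 arrays in each of 9 groups. The groups allow the question of how far chemical mimics of hypoxia resemble low oxygen in their effect on transcripts, and how early. Signals at 2 h and at 24 h were on different scales, so levels are compared only within a time point, and the 24 h tests of hypoxia used 1 array. Array medians were 59.2 to 64.6 at 2 h and 95.05 to 108.1 in the 24 h tests, and medians of background probe sets were 5.7 to 22.4 and 22 to 25.6 on the scales of these times. Gene values with ± below are log2 fold changes with SE unless called signals, and p-values beside counts of list members are the adjusted p of camera for the list. The standard deviation (SD) of the log2 difference between replicates was 0.312 to 0.373 at 2 h and 0.133 to 0.216 at 24 h. The smaller spread at 24 h allowed smaller changes to pass the test. The all-array model, which mixed the scales, gave 4, 0 and 0 calls for hypoxia, cobalt and deferoxamine at 2 h, against 365, 16 and 396 in the fits used here, with 239, 144 and 222 probe sets at unadjusted p under 0.05 in limma. At 24 h it gave 1369 (67 higher), 61 (42 higher), 388 (210 higher) and 34 (17 higher) calls for hypoxia, cobalt, deferoxamine and nickel, against 2442, 1979, 3719 and 2870. In 24 h controls the signals of IGF2 (11.95) and ENO2 (22.05) were not above the background medians of 22.6 and 22.1, so their fold sizes against control at 24 h depend on the offset and are lower bounds.

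**Figure D1:**
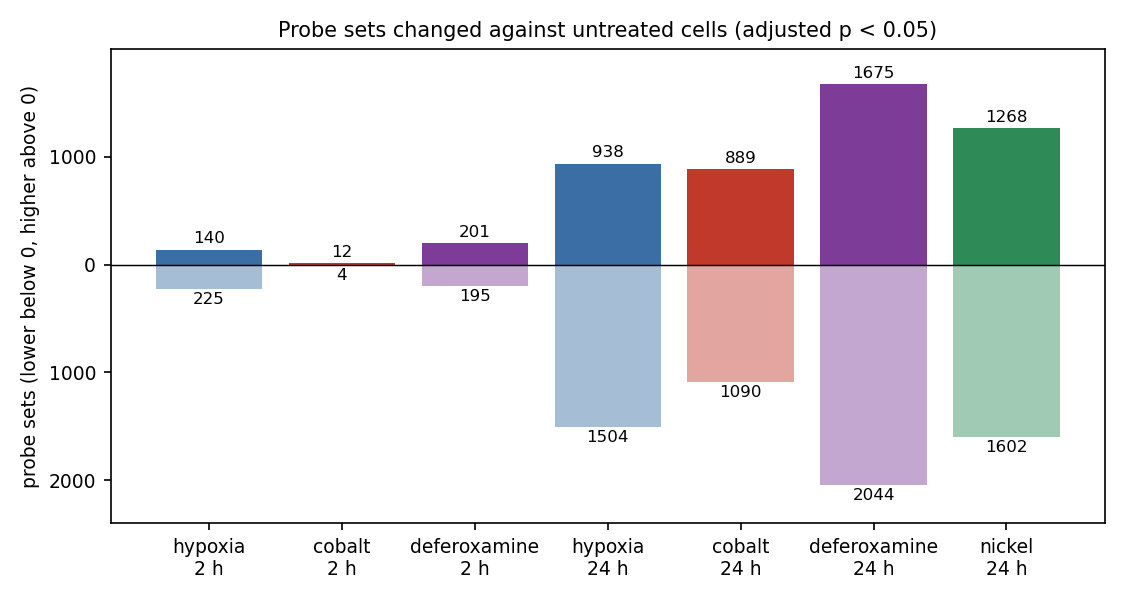
Number of probe sets that passed the test (adjusted p under 0.05) higher or lower than control for each treatment and time, among 7535 tested. Cobalt at 2 h changed 16 probe sets and deferoxamine at 24 h changed 3719.

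Cobalt against control at 2 h asked for the early response to a metal ion. DDIT4, an inhibitor of the growth kinase complex mTORC1, rose with a log2 fold change of 1.87 ± 0.11, from a mean signal of 265 ± 24.2 to 1014 ± 125 (SD, n = 2). BHLHE40, a transcriptional repressor, rose by 1.30 ± 0.09 and ZFP36, a protein that promotes decay of AU-rich transcripts, rose by 1.12 ± 0.10. ADM, the vasodilator peptide adrenomedullin, rose by 1.82 ± 0.17, a call that ended without cobalt replicate 1 (adjusted p = 0.0592). IGFBP1, a secreted binder of insulin-like growth factors, rose by 1.22 ± 0.15, and the zinc exporter SLC30A1 had a log2 fold change of −0.96 ± 0.12. In total 16 probe sets passed the test in limma, 12 higher and 4 lower. Of 30 measured HIF targets outside glycolysis, 6 rose, 0 fell and 24 did not pass, and adjusted over the list alone 10 rose. They shifted up as a list (adjusted p = 3.45e-13). KDM3A, a histone demethylase, had a log2 fold change of 1.03 ± 0.14 and the angiogenic factor VEGFA of 0.79 ± 0.12. Of 22 glycolytic genes 0 passed in limma, with 4 at unadjusted p under 0.05.

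Other lists that shifted up after 2 h of cobalt did so with few single-gene calls. Of 16 oxidative stress genes 0 passed in limma, 7 had an unadjusted p under 0.05 and 6 rose with adjustment over the list alone, at a list adjusted p of 2.58e-05 (adjusted p = 0.0871 with an estimated correlation). The haem-degrading enzyme HMOX1 stood at 1.70 ± 0.30 (adjusted p = 0.0749). Immediate early genes (1 of 21 rose, 6 over the list alone) had an adjusted p of 4.86e-04 (adjusted p = 0.0871 with an estimated correlation). Dioxygenases had 1 of 21 higher and the integrated stress response 1 of 19, with list adjusted p of 0.00181 and 0.035 (adjusted p = 0.0871 and 0.253 with an estimated correlation). Downward list shifts were found for cytosolic ribosomal proteins (0 of 31 passed in limma, 2 at unadjusted p under 0.05, list adjusted p = 0.00663), inflammatory genes (1 of 13 fell, 0.0149) and cholesterol synthesis (0 of 14 passed, 1 at unadjusted p under 0.05, 0.0307). These gave an adjusted p = 0.593, 0.158 and 0.253 with an estimated correlation, and for the ribosomal proteins an adjusted p of 0.22 and a median of −0.04 against −0.10 under quantile normalization. The calls of IGFBP1, SLC30A1, KDM3A and VEGFA, with highest adjusted p of 0.143, 0.143, 0.211 and 0.237, ended without any 1 of control replicate 1, control replicate 2, cobalt replicate 1 or cobalt replicate 2. Without cobalt replicate 1, and with variances without a trend, 4 probe sets passed, 3 of them among the 16, without each of the other 3 arrays 4 of the 16 passed, the lack of a level filter gave 10, a filter at the 60th percentile gave 32, and quantile normalization gave 25 (15 higher, 10 lower).

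Deferoxamine against control at 2 h asked for the early response to iron chelation. ADM rose by 2.42 ± 0.17, from a signal of 154 ± 33 to 885 ± 30.9 (SD, n = 2), and DDIT4 rose by 2.28 ± 0.11. NPPB, the natriuretic peptide BNP, rose by 2.09 ± 0.14, BHLHE40 by 1.61 ± 0.09 and KDM3A by 1.61 ± 0.14. IGF2, insulin-like growth factor 2, fell with a log2 fold change of −1.38 ± 0.13. In limma, 201 probe sets rose and 195 fell. Of 30 HIF targets 16 rose, 1 fell and 13 did not pass, with 20 higher over the list alone and a list adjusted p of 7.29e-12. VEGFA rose by 0.96 ± 0.12, with the call lost without deferoxamine replicate 1 (adjusted p = 0.0582). NDRG1, a hypoxia-induced growth regulator, rose by 1.03 ± 0.16, with the call lost without control replicate 1, deferoxamine replicate 1 or deferoxamine replicate 2 (highest adjusted p = 0.0883). Glycolytic genes showed no list shift at 2 h (2 of 22 rose, 1 fell, adjusted p = 0.361).

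Cytosolic ribosomal proteins fell as a list after 2 h of deferoxamine, with 15 of 31 lower (23 over the list alone), 0 higher and a median log2 fold change of −0.35. Their list adjusted p was 3.95e-10 (adjusted p = 0.302 with an estimated correlation). Under quantile normalization the median was −0.05, and the list did not pass (adjusted p = 0.148). Cell cycle genes shifted up (9 of 38 rose, 0.00258), as did dioxygenases (4 of 21 rose, 1 fell, 0.00645), with an adjusted p = 0.155 and 0.155 with an estimated correlation. Inflammatory genes shifted down (1 of 13 fell, 0.00821), with an adjusted p = 0.155 with an estimated correlation. Among single genes, HERPUD1, an endoplasmic reticulum stress protein, rose by 1.00 ± 0.11 and ZFP36 by 1.18 ± 0.10. The count of 396 fell to 77 without control replicate 1, 107 without control replicate 2, 46 (21 higher, 25 lower) without deferoxamine replicate 1 and 70 (27 higher, 43 lower) without deferoxamine replicate 2. It was 237 without the level filter and 68 with variances without a trend.

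Hypoxia against control at 2 h asked for the early response to low oxygen itself. The largest falls that held in every leave-one-out fit were in TMEM259, a membrane protein of the endoplasmic reticulum, with a log2 fold change of −2.21 ± 0.19 and signals of 24.2 ± 8.13 against 169 ± 5.87 (SD, n = 2), in DUSP8, a phosphatase of stress-activated kinases (−2.12 ± 0.20), and in SH3GL1, an endocytosis protein (−1.84 ± 0.21). JUNB, a subunit of the transcription factor AP-1, fell (−1.08 ± 0.08), as did the chemokines CXCL8 (−0.86 ± 0.08) and CCL20 (−0.65 ± 0.07) and ZFP36 (−0.79 ± 0.10). SDHC, a subunit of succinate dehydrogenase, rose by 0.86 ± 0.10. In limma, 140 probe sets rose and 225 fell. Several known hypoxia genes did not pass the test. ADM stood at 0.39 ± 0.17 (adjusted p = 0.235), NDRG1 at 0.11 ± 0.16, VEGFA at −0.27 ± 0.12 and BNIP3, a mitophagy receptor, at 0.04 ± 0.12. Of 30 HIF targets 1 rose and 1, IGFBP1, fell (−0.71 ± 0.15), a call that ended without control replicate 1, control replicate 2 or hypoxia replicate 2 (highest adjusted p = 0.154), with a list adjusted p of 0.941, and of 22 glycolytic genes 1 rose.

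Immediate early genes shifted down after 2 h of hypoxia, with 5 of 21 lower and 0 higher (list adjusted p = 0.0252, and adjusted p = 0.401 with an estimated correlation). Hepatocyte secreted proteins shifted up (4 of 22 rose, 0.0252), as did cell cycle genes (5 of 38, 0.0252). For the latter pair, in that order, adjusted p = 0.514 and 0.401 with an estimated correlation, and under quantile normalization the 3 lists had an adjusted p of 0.0584, 0.0705 and 0.0705. APOA1, the main protein of high-density lipoprotein, rose by 0.49 ± 0.07, with the call lost without control replicate 1 (adjusted p = 0.0627). CEBPB, a liver transcription factor, fell (−0.83 ± 0.12), with the call lost without hypoxia replicate 2 (adjusted p = 0.0509). The count of 365 fell to 81 without control replicate 1, 135 without control replicate 2, 155 without hypoxia replicate 1 and 110 without hypoxia replicate 2. It was 234 without the level filter and 83 with variances without a trend.

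At 2 h the treatments were then compared directly, to ask where a mimic and hypoxia differed. Deferoxamine exceeded hypoxia for DDIT4 by 2.31 ± 0.11, for ADM by 2.02 ± 0.17, for VEGFA by 1.23 ± 0.12 and for JUNB by 1.35 ± 0.08. Cobalt exceeded hypoxia for DDIT4 by 1.91 ± 0.11, for ADM by 1.42 ± 0.17, for VEGFA by 1.07 ± 0.12, for ZFP36 by 1.91 ± 0.10 and for CXCL8 by 0.62 ± 0.08. HIF targets were higher than under hypoxia as a list with deferoxamine (10 of 30 higher, 0 lower, 5.1e-15, and adjusted p = 0.0147 with an estimated correlation) and with cobalt (10 higher, 1 lower, 2.24e-07, and adjusted p = 0.0531 with an estimated correlation). Immediate early genes were likewise higher with cobalt (10 of 21, 5.13e-06) and with deferoxamine (5, 1.58e-05), with an adjusted p = 0.0531 and 0.0694 with an estimated correlation. Between the mimics, IGF2 was higher under cobalt by 1.47 ± 0.13 and the growth regulator MYC by 1.16 ± 0.12, while NPPB was lower (−1.38 ± 0.14) and HIF targets were lower as a list (1 lower, 1 higher, 0.00452, and adjusted p = 0.203 with an estimated correlation).

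In limma, 481 probe sets differed between cobalt and hypoxia at 2 h, 79 between deferoxamine and hypoxia and 245 between cobalt and deferoxamine. Without cobalt replicate 2, hypoxia replicate 1 or hypoxia replicate 2 the cobalt and hypoxia count fell to 212, 215 and 196. Without deferoxamine replicate 1, deferoxamine replicate 2 or hypoxia replicate 2 the deferoxamine and hypoxia count fell to 17, 22 and 20, and without hypoxia replicate 1 its split of 52 higher and 27 lower became 30 and 33. Without cobalt replicate 1, cobalt replicate 2, deferoxamine replicate 1 or deferoxamine replicate 2 the cobalt and deferoxamine count fell to 159 (72 higher, 87 lower, against 144 and 101), 49, 24 and 48. Variances without a trend gave 187, 23 and 48, the lack of a level filter gave 43 and 124 for the comparisons with deferoxamine, and a filter at the 60th percentile gave 153 for deferoxamine against hypoxia.

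Hypoxia against control at 24 h asked for the later response to low oxygen, with 1 hypoxia array against 2 controls. NDRG1 rose by 6.18 ± 0.13, from a signal of 77.8 ± 5.02 (SD, n = 2) to 6770, and IGF2 rose by at least 6.83, to a signal of 3145. ADM rose by 2.95 ± 0.15, INHBB, a subunit of activin B, by 2.40 ± 0.10, and PDK1, a kinase that slows entry of pyruvate into the tricarboxylic acid cycle, by 2.23 ± 0.18. CGA, the alpha subunit of glycoprotein hormones, fell (−3.18 ± 0.12, signal 106 against 1085 ± 23.2), as did the mitochondrial enzyme OAT (−1.80 ± 0.08) and HABP2, a plasma protease (−2.04 ± 0.25). In limma, 938 probe sets rose and 1504 fell, 154 and 251 of them at least 2-fold, against 1128 and 1257 under quantile normalization. Of 27 HIF targets 19 rose, 1 fell and 7 did not pass, with VEGFA at 2.10 ± 0.13, BNIP3 at 1.42 ± 0.09 and the collagen prolyl hydroxylase P4HA1 at 1.77 ± 0.09 (list adjusted p = 3.46e-11, and adjusted p = 0.135 with an estimated correlation). Glycolysis had 13 of 22 genes higher and 0 lower, among them aldolase ALDOA (1.33 ± 0.09), lactate dehydrogenase LDHA (1.12 ± 0.08) and PGK1 (0.48 ± 0.07), with a list adjusted p of 6.04e-06 (adjusted p = 0.135 with an estimated correlation). Dioxygenases had 9 of 22 higher (0.00289, and adjusted p = 0.139 with an estimated correlation).

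A further 3 lists shifted down under 24 h of hypoxia. Of 15 ribosome biogenesis genes 12 fell and 0 rose (3.76e-05, and adjusted p = 0.139 with an estimated correlation), including the RNA polymerase subunit POLR1C (−1.21 ± 0.13) and RRS1 (−1.20 ± 0.15). Of 20 genes of the integrated stress response 12 fell and 0 rose (0.00106, median −0.36, or −0.23 under quantile normalization, and adjusted p = 0.139 with an estimated correlation), including asparagine synthetase ASNS (−1.64 ± 0.10), the folate enzyme MTHFD2 (−1.46 ± 0.09) and the transcription factor DDIT3 (−1.09 ± 0.10). Of 34 oxidative phosphorylation genes 19 fell and 2 rose (0.00109, and adjusted p = 0.139 with an estimated correlation), with the complex I subunit NDUFA5 at −1.19 ± 0.11 and isocitrate dehydrogenase IDH2 at 1.19 ± 0.08. The iron transporter TF rose (1.47 ± 0.08), and 3 of 8 iron genes rose with no list shift (adjusted p = 0.474). Hepatocyte secreted proteins moved both ways (7 of 22 rose, 5 fell, 0.257), with APOA1 at 1.31 ± 0.08 and prothrombin F2 at 1.35 ± 0.10. Cell cycle genes likewise had 13 of 38 lower and 4 higher (0.246), with CDK1 at −0.89 ± 0.09. HIF1A itself stood at −0.35 ± 0.14 (adjusted p = 0.0805) and the glucose transporter SLC2A1 at 0.04 ± 0.09, on a signal of 73.9. EPO, erythropoietin, lay below the filter and was not tested, with a signal of 70.7 on the hypoxia array and 36.4 ± 0.283 (SD, n = 2) in controls.

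Cobalt against control at 24 h asked for the later response to the metal ion. NDRG1 rose by 6.73 ± 0.10, from 77.8 ± 5.02 to 9932 ± 472 (SD, n = 2), and ADM rose by 5.02 ± 0.12. ENO2, a glycolytic enolase, rose by at least 3.99, TXNIP, a thioredoxin-binding protein, by 3.29 ± 0.12 and IGFBP1 by 3.27 ± 0.10. IGF2 rose by at least 3.63, to a signal of 330 ± 49.4 (SD, n = 2). The chemokine CXCL1 fell (−2.43 ± 0.11), as did HABP2 (−2.93 ± 0.20) and the growth factor receptor FGFR2 (−1.81 ± 0.15). In limma, 889 probe sets rose and 1090 fell. Of 27 HIF targets 25 rose and 1 fell (median 2.13, 5.51e-25), with BNIP3 at 3.70 ± 0.07 and P4HA1 at 3.70 ± 0.08, and of 22 glycolytic genes 17 rose and 0 fell (3.65e-15). Of 8 metallothionein and zinc export genes 5 rose and 0 fell (1e-04), led by the metal-binding protein MT1X (2.77 ± 0.14, signal 352 ± 90.6 against 37.5 ± 4.6). Of 17 oxidative stress genes 10 rose and 1 fell (5.31e-06), including HMOX1 (2.57 ± 0.09), the glutathione synthesis enzyme GCLC (1.94 ± 0.10) and thioredoxin reductase TXNRD1 (1.29 ± 0.07). Iron genes had 5 of 8 higher (1.12e-04), including the transferrin receptor TFRC (0.68 ± 0.06) and the ferroxidase CP (2.14 ± 0.14), and dioxygenases 8 of 22 (1.12e-04).

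Cholesterol synthesis fell under 24 h of cobalt in 11 of 15 genes, with 0 higher (1.01e-08). HMGCS1, an early enzyme of the pathway, stood at −1.48 ± 0.10 and ACAT2 at −1.51 ± 0.09. Inflammatory genes had 6 of 13 lower and 0 higher (7.36e-04), including CCL20 (−1.13 ± 0.06), and ribosome biogenesis had 7 of 15 lower and 1 higher (0.0044), each at adjusted p = 0.194 with an estimated correlation. The integrated stress response had 7 of 20 lower (0.03) and cytosolic ribosomal proteins 6 of 31 higher (0.0103, or 0.0869 under quantile normalization, with a median of 0.05 against 0.11), with an adjusted p = 0.258 and 0.543 with an estimated correlation. Hepatocyte secreted proteins did not shift (7 rose, 9 fell, 0.901), and their median and mean differed in sign. Fibrinogen FGA rose (1.53 ± 0.11) while kininogen KNG1 fell (−0.86 ± 0.07). The count of 1979 was 1217 without control replicate 1 and 1234 without control replicate 2.

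Deferoxamine against control at 24 h asked for the later response to iron chelation, which changed the most probe sets. NDRG1 rose by 7.65 ± 0.10, from 77.8 ± 5.02 to 18741 ± 26.2 (SD, n = 2), ENO2 by at least 6.08 and CXCR4, a chemokine receptor, by 5.98 ± 0.12. IGF2 rose by at least 5.92, the collagen prolyl hydroxylase P4HA2 by 4.78 ± 0.10 and IGFBP1 by 4.68 ± 0.10. EIF4E, the translation factor that binds the messenger RNA cap, fell (−2.99 ± 0.09), as did the arginine methyltransferase PRMT3 (−3.73 ± 0.17). In limma, 1675 probe sets rose and 2044 fell, 495 and 542 of them at least 2-fold. Of 27 HIF targets 25 rose and 0 fell (median 2.99, 6.06e-18), and of 22 glycolytic genes 19 rose and 0 fell (2.17e-10), with phosphoglucomutase PGM1 at 3.65 ± 0.12, ALDOA at 2.23 ± 0.07 and LDHA at 1.62 ± 0.07. TFRC rose by 0.89 ± 0.06 and HMOX1 by 1.01 ± 0.09, while HIF1A fell (−0.45 ± 0.11), a call that ended without control replicate 2 (adjusted p = 0.0553).

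Further lists shifted after 24 h of deferoxamine. Ribosome biogenesis had 14 of 15 genes lower and 1 higher (1.15e-05, and adjusted p = 0.0835 with an estimated correlation), with the small-subunit processing protein UTP20 at −2.25 ± 0.15. Immediate early genes had 12 of 18 higher and 2 lower (1.53e-04, and adjusted p = 0.0744 with an estimated correlation), including FOS (3.11 ± 0.11), JUNB (2.73 ± 0.10) and ATF3 (3.38 ± 0.17). Targets of p53 had 7 of 13 higher and 2 lower (0.015, and adjusted p = 0.256 with an estimated correlation), including the cell cycle inhibitor CDKN1A (1.54 ± 0.10), the stress cytokine GDF15 (2.84 ± 0.08) and the DNA repair protein DDB2 (2.44 ± 0.25). The cell cycle list did not shift (11 rose, 17 fell, 0.301). Oxidative phosphorylation (21 of 34 fell, 4 rose, 0.00598) and cholesterol synthesis (9 of 15 fell, 0.00172) shifted down and dioxygenases up (11 of 22 rose, 0.00172), with an adjusted p = 0.162, 0.0835 and 0.0835 with an estimated correlation. Among hepatocyte secreted proteins 8 of 22 fell, 4 rose and the list did not shift (0.424), with apolipoprotein APOB at −1.58 ± 0.06 and KNG1 at −2.37 ± 0.07. Heat shock genes had 8 of 11 lower with a list adjusted p of 0.0886, which was 0.049 under quantile normalization.

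Nickel against control at 24 h asked for the response to a further metal ion, on arrays whose labels do not say whether they share a batch with the controls. IGF2 rose by at least 6.45, NDRG1 by 5.67 ± 0.10 (signal 4785 ± 743 against 77.8 ± 5.02, SD, n = 2) and DDIT4 by 2.76 ± 0.09. PROX1, a hepatic transcription factor, rose by 2.23 ± 0.28 and PLOD2, a collagen lysyl hydroxylase, by 1.97 ± 0.09. HABP2 fell (−3.10 ± 0.20), as did CGA (−2.62 ± 0.10), CXCL8 (−2.57 ± 0.09) and the adhesion molecule ICAM1 (−1.82 ± 0.21). In limma, 1268 probe sets rose and 1602 fell, but without nickel replicate 2 the split was 1612 and 1471. Nickel replicate 1, then alone, had the highest median (108.1) and background median (25.6) of the 24 h arrays. Of 27 HIF targets 20 rose and 0 fell (1.53e-10), with ADM at 1.92 ± 0.12 and VEGFA at 1.65 ± 0.11, of 22 glycolytic genes 13 rose and 0 fell (3e-05), and of 22 dioxygenases 9 rose and 1 fell (0.00359), each at adjusted p = 0.15 with an estimated correlation. Ribosome biogenesis (11 of 15 lower, 1 higher, 9.26e-04) and oxidative phosphorylation (19 of 34 lower, 4 higher, 0.00254) shifted down, both at adjusted p = 0.199 with an estimated correlation. The integrated stress response (8 of 20 lower, 2 higher) and inflammatory genes (7 of 13 lower, 2 higher) shifted down at 0.0365 each, with an adjusted p = 0.389 and 0.459 with an estimated correlation and 0.124 and 0.0577 under quantile normalization. Of 8 metallothionein and zinc export genes 0 rose and 1 fell in limma, with 0 higher and 2 lower at unadjusted p under 0.05, and MT1X did not pass (adjusted p = 0.0592), with a nickel signal of 25.1 that was at background. HMOX1 rose by 0.35 ± 0.09, with the call lost without control replicate 1 (adjusted p = 0.101).

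**Figure D2:**
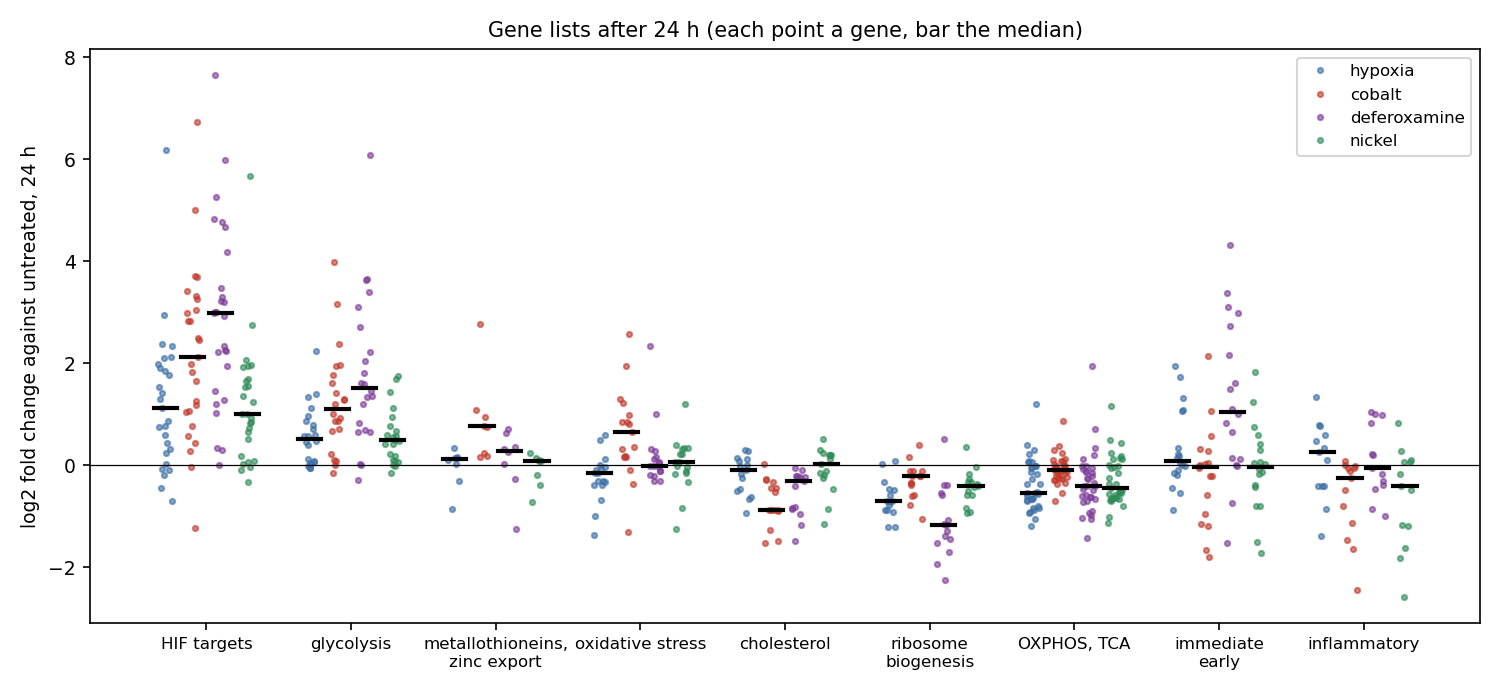
Log2 fold change against control at 24 h for the members of 9 gene lists under 4 treatments, with points for genes and bars for list medians. The median of HIF targets was 1.12 under hypoxia, 2.13 under cobalt, 2.99 under deferoxamine and 1.00 under nickel.

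Across the 7 comparisons with controls, camera called 48 list shifts with the preset correlation. With an estimated correlation 11 held. These were HIF targets under cobalt and deferoxamine at both times, glycolysis under cobalt and deferoxamine at 24 h, and metallothioneins, iron handling, dioxygenases, oxidative stress and cholesterol synthesis under cobalt at 24 h. The shifts of dioxygenases and HIF targets are not independent, since the lists share members. Fatty acid oxidation genes did not shift under any treatment, with 3 of 15 higher and 2 lower under hypoxia at 24 h and 5 and 3 under deferoxamine. Heat shock genes did not shift under hypoxia at 24 h either (5 of 11 fell, 1 rose), nor did p53 targets (2 of 13 rose, 3 fell) or cytosolic ribosomal proteins (3 of 31 rose, 5 fell).

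Nickel against hypoxia at 24 h asked where this metal departed from low oxygen. UGDH, which makes UDP-glucuronate, was higher under nickel by 1.48 ± 0.11 and TXNRD1 by 1.06 ± 0.09. ICAM1 was lower (−2.59 ± 0.26), as were CXCL8 (−1.20 ± 0.10) and CXCL1 (−1.23 ± 0.14). ADM was also lower (−1.03 ± 0.15), with the call lost without nickel replicate 1 (adjusted p = 0.0867). In limma, 127 probe sets were higher and 104 lower. HIF targets did not differ as a list (2 of 27 higher, 2 lower, 0.336) and LDHA differed by 0.01 ± 0.08. Inflammatory genes (5 of 13 lower, 0 higher, 1.72e-12) and immediate early genes (7 of 18 lower, 1 higher, 2.88e-07) were lower under nickel, and oxidative stress genes were higher (5 of 17, 13 over the list alone, 8.83e-05), each at adjusted p = 0.0648 with an estimated correlation. The integrated stress response (3 of 20 higher, 0.00646) and ribosome biogenesis (1 of 15 higher, 0.0148) were higher, with an adjusted p = 0.311 and 0.408 with an estimated correlation. The count of 231 was 56 without nickel replicate 1, 80 (28 higher, 52 lower) without nickel replicate 2 and 126 with variances without a trend, while quantile normalization gave 209 (78 higher, 131 lower) and the lack of a level filter 197 (90 higher, 107 lower). The all-array model gave 0 calls in limma, with 2937 probe sets at unadjusted p under 0.05.

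Cobalt against hypoxia at 24 h asked the same of cobalt. ENO2 was higher under cobalt by 3.13 ± 0.23, MT1X by at least 3.07, HMOX1 by 2.67 ± 0.11 and ADM by 2.07 ± 0.15. IGF2, which cobalt also raised against control, was lower than under hypoxia (−3.20 ± 0.17). PROX1 (−2.51 ± 0.35), F2 (−1.70 ± 0.10) and HMGCS1 (−1.78 ± 0.12) were lower as well. In limma, 1608 probe sets were higher and 1195 lower, against 1382 and 1355 under quantile normalization. HIF targets (20 of 27 higher, 5 lower, 2.82e-05), glycolysis (15 of 22 higher, 5.35e-05), oxidative stress (13 of 17 higher, 2.82e-05) and metallothioneins (6 of 8 higher, 0.00499) were higher under cobalt, and cholesterol synthesis was lower (7 of 15, 1.87e-04). For each of these 5 lists adjusted p = 0.109 with an estimated correlation. Inflammatory genes were lower (10 of 13, 1 higher, 1.87e-04) and oxidative phosphorylation genes higher (16 of 34, 4 lower, 0.00787), with an adjusted p = 0.158 with an estimated correlation for each. VEGFA was lower under cobalt (−0.44 ± 0.13), with the call lost without cobalt replicate 1 or cobalt replicate 2 (highest adjusted p = 0.0771).

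Deferoxamine against hypoxia at 24 h asked the same of iron chelation. CXCR4 was higher under deferoxamine by 5.96 ± 0.15, ENO2 by 5.22 ± 0.23, CGA by 4.49 ± 0.12 and GDF15 by 2.17 ± 0.10. PLK1 was lower (−2.36 ± 0.10), as were the sialyltransferase ST6GAL1 (−2.72 ± 0.08) and the antimicrobial peptide DEFB1 (−2.99 ± 0.21), while VEGFA differed by 0.14 ± 0.13. In limma, 1347 probe sets were higher and 1150 lower, a balance that turned to 1222 and 1294 under quantile normalization. HIF targets (24 of 27 higher, 0 lower, 1.93e-15) and glycolysis (17 of 22 higher, 0 lower, 1.22e-09) were higher, each at adjusted p = 0.0552 with an estimated correlation. Immediate early genes were higher (11 of 18, 2 lower, 0.00356) and hepatocyte secreted proteins lower (10 of 22, 2 higher, 0.00283), each at adjusted p = 0.112 with an estimated correlation. Targets of p53 were higher (6 of 13, 0.0105) and ribosome biogenesis lower (9 of 15, 0.00396), with an adjusted p = 0.191 and 0.186 with an estimated correlation. The all-array model gave 724 calls (666 higher, 58 lower) here and 1294 (1229 higher, 65 lower) for cobalt against hypoxia.

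Comparisons among the mimics at 24 h asked whether they differed from one another. In limma, 3599 probe sets differed between cobalt and deferoxamine (1926 higher, 1673 lower) and 3005 between nickel and cobalt (1394 higher, 1611 lower). Without nickel replicate 2 the latter split turned to 1658 and 1491. Immediate early genes were lower under cobalt than under deferoxamine (15 of 18 lower, 1 higher, 1.56e-06, and adjusted p = 0.0907 with an estimated correlation), with FOS at −3.06 ± 0.11. Inflammatory genes were lower under cobalt too (10 of 13, 9.12e-04, and adjusted p = 0.19 with an estimated correlation). HIF targets were lower under nickel than under cobalt (19 of 27 lower, 3 higher, 2.87e-07), with ADM at −3.09 ± 0.12, and cholesterol synthesis genes were higher (11 of 15, 0 lower, 3.47e-05), each at adjusted p = 0.0835 with an estimated correlation. Metallothionein and zinc export genes were lower under nickel (6 of 8, 0.00121, and adjusted p = 0.0835 with an estimated correlation), with MT1X at −3.14 or below, since its nickel signal of 25.1 was at background.

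**Figure D3:**
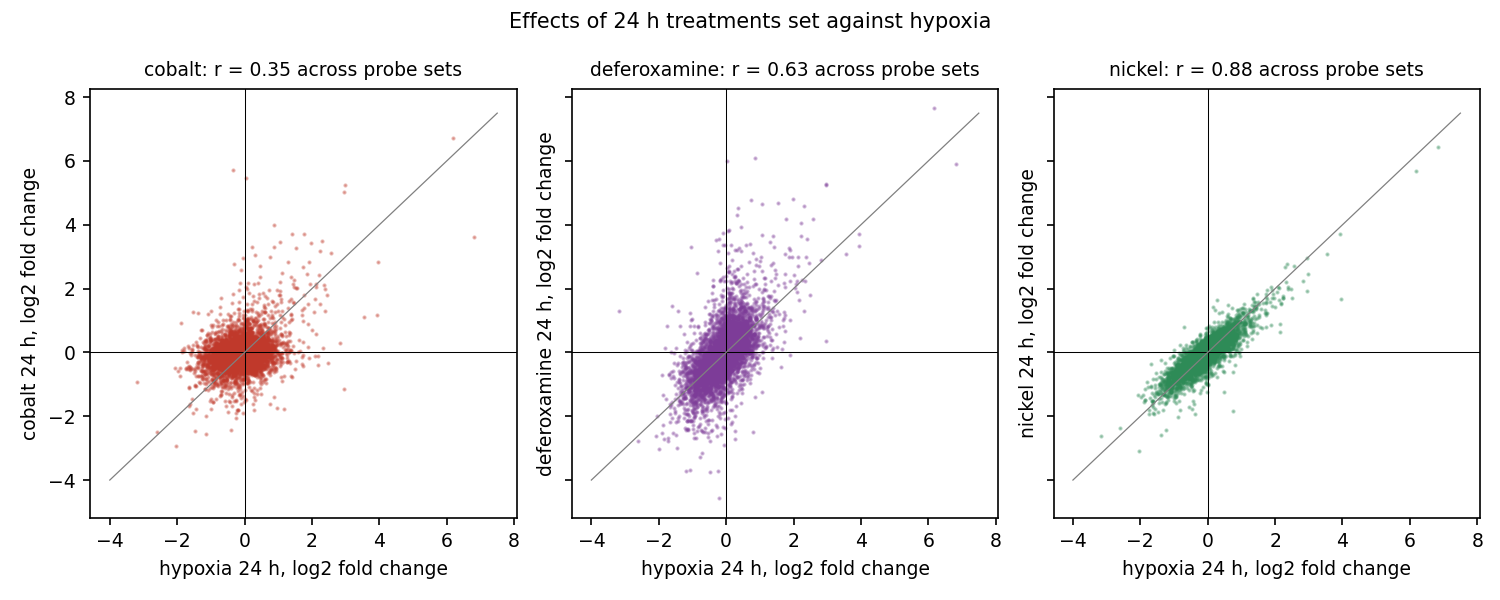
Log2 fold change against control at 24 h under cobalt, deferoxamine and nickel (vertical axes) plotted against hypoxia (horizontal axes), 1 point per probe set, n = 7535. The Pearson correlations were 0.355, 0.626 and 0.880.

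How alike the treatments were was measured by Pearson correlations across 7535 probe sets, which are not independent replicates. Effects share control arrays, and simulations of unchanged groups gave 0.409 for pairs with hypoxia at 24 h and about 0.5 for other pairs. At 24 h the correlation with hypoxia was 0.880 for nickel, 0.626 for deferoxamine and 0.355 for cobalt. Of 938 probe sets raised by hypoxia, nickel raised 726 and lowered 5, deferoxamine raised 609 and lowered 55 and cobalt raised 259 and lowered 125. The shared controls add to such overlaps, for which no value without effect was simulated. NDRG1, BNIP3 and LDHA rose under all 4 treatments. The covariance of each pair of effects at 24 h lay above the highest simulated value, 0.0821 against 0.00749 for hypoxia and cobalt. At 2 h the correlations were 0.611 for hypoxia and deferoxamine, 0.456 for cobalt and deferoxamine and 0.316 for hypoxia and cobalt. Without replicate 2 of the control the last was 0.538, and without replicate 1 of cobalt the correlation of cobalt and deferoxamine was 0.275. Hypoxia and deferoxamine at 2 h raised 62 probe sets in common and lowered 83, while of the 12 raised by cobalt deferoxamine raised 9, among them ADM, DDIT4 and BHLHE40.

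The response at 2 h was set beside that at 24 h for 6164 probe sets tested at both times. For cobalt, 10 of the 12 probe sets raised at 2 h were also raised at 24 h and 0 were lowered, and of 4 lowered at 2 h, 3 were lowered and 0 raised. For deferoxamine, 116 of 200 raised at 2 h were raised at 24 h and 30 were lowered, and of 186 lowered at 2 h, 81 were lowered and 58 raised. For hypoxia, 28 of 136 raised at 2 h were raised at 24 h and 36 were lowered, and of 220 lowered at 2 h, 40 were lowered and 104 raised. Independent lists of these sizes would share 1.64 raised and 0.692 lowered probe sets for cobalt. They would share 50.8 and 59.7 for deferoxamine and 18.7 and 52.8 for hypoxia. No such value was computed for probe sets changed in opposite directions. The correlation of effects across probe sets was −0.144 for hypoxia, 0.158 for cobalt and 0.124 for deferoxamine. Under hypoxia JUNB went from −1.08 ± 0.08 to 1.32 ± 0.12 and ZFP36 from −0.79 ± 0.10 to 1.94 ± 0.11. Under deferoxamine IGF2 went from −1.38 ± 0.13 to at least 5.92. Its control signal was 543 ± 13.4 at 2 h and 11.95 ± 2.9 at 24 h (SD, n = 2), the latter not above background. Because the scales differ, a change of IGF2 in controls between the times was not tested. Its turn may therefore reflect the controls as well as the treatment.

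Markers of other cells were measured because a culture can hold more than the named line. Of 10 fibroblast markers on the array, the highest in controls were LUM at 2 h (43.1) and COL1A1 at 24 h (737). Of 3 tested at 2 h, 0 passed in limma, with 0 at unadjusted p under 0.05 under hypoxia and cobalt and 1 under deferoxamine. At 24 h COL1A1 rose under hypoxia (0.52 ± 0.15), with the call lost without control replicate 2 (adjusted p = 0.101), and LUM fell (−1.47 ± 0.20), as it did under cobalt (−1.04 ± 0.17) and nickel (−1.31 ± 0.17). COL1A1 also rose under nickel (0.41 ± 0.12), with the call lost without control replicate 1, control replicate 2 or nickel replicate 1 (highest adjusted p = 0.136). FBN1 rose under deferoxamine (1.18 ± 0.15) and fell under cobalt (−0.46 ± 0.15), the latter call being lost without any 1 of control replicate 1, control replicate 2, cobalt replicate 1 or cobalt replicate 2 (highest adjusted p = 0.22). Of 13 leukocyte markers CD68 was highest at 2 h (144) and LYZ at 24 h (1289), where LYZ fell under cobalt (−0.96 ± 0.09) and rose under deferoxamine (0.45 ± 0.09). Endothelial markers had 1 of 7 above the filter at 2 h, PECAM1 (64.2), and 0 at 24 h, so the list was not tested. Erythroid markers reached 234 at 2 h (ALAS2) and 189 at 24 h (HBB), and HBB stood at 0.70 ± 0.26 under hypoxia (adjusted p = 0.0722) and rose under nickel (0.63 ± 0.22), with the call lost without control replicate 1 or nickel replicate 1 (highest adjusted p = 0.332).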

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

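The predictions for the trimmed mean, for a mislabelled sample, for chance values of the control arrays and for all probe sets shared by nickel and hypoxia were chosen only after the results were seen. Predictions for variation between arrays, for an early form of the 24 h response and for the smaller set shared by nickel and hypoxia were written before their values were computed.

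Replicate 1 of hypoxia at 24 h drew attention because neither main fit used it and yet it carried high signals of some hypoxia genes. NDRG1 stood at 1052.7, against at most 281.3 on the 2 h arrays of the same scale, and EPO at 160.1 against at most 15.2, while ADM (459.5 against 907.1) and PGK1 (5120.9 against 5740.7) lay below the highest 2 h array. The authors appear to have processed this array as they did the 2 h arrays, since its trimmed mean of 200.094 differed by at most 0.00999% from theirs. A sample from 2 h under the wrong label is unlikely, since of 105 genes raised at least 2-fold on replicate 2, 67 lay above all 8 of the 2 h arrays (63.8%, exact 95% interval 53.9% to 73.0%), against 3 of 195 lowered genes. The prediction took 11.1% as the share to be met by chance, but 33.3% of all 8225 genes lay that high on this array. The interval lies above this as well. Intervals here and for the nickel sets below treat genes or probe sets of 1 array as independent draws. They measure no spread between arrays.

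Hypoxia changed 140 probe sets in opposite directions at 2 h and 24 h, 36 raised and then lowered and 104 lowered and then raised. Deferoxamine changed 88 in this way, 30 and 58 in that order. These were flagged as differences between groups, but the count that independent lists would give in opposite directions was not computed. The counts are therefore not shown to exceed it. For deferoxamine the counts in the same direction (116 raised, 81 lowered) lay above those of independent lists (50.8 and 59.7). The test of the difference between the separate fits adds nothing, since choosing probe sets that passed in opposite directions fixed its outcome. At 2 h the effects of hypoxia and deferoxamine shared many probe sets that are not HIF targets. Variation that is also present between replicates is a candidate explanation. The hypoxia effect correlated with the difference between the cobalt replicates at −0.0602 across probe sets (deferoxamine, −0.157). This covers only variation of the kind seen between the cobalt arrays. Differences between the control, hypoxia or deferoxamine replicates were not used, so variation between arrays cannot be excluded. The covariance was 0.0728, against at most 0.0259 in 100 simulations. These drew noise independently for each probe set, and such noise in the shared control arrays is unlikely to account for it. A deviation common to both control arrays was not simulated. The 2 h hypoxia effect did not rise with the 24 h hypoxia effect (correlation −0.144). This cannot exclude an early form, since the 2 times are on separate scales and cobalt and deferoxamine gave only 0.158 and 0.124. A difference in handling between whole groups could not be separated from treatment, because each treatment is 1 group.

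Nickel resembled hypoxia at 24 h with a covariance of effects of 0.210, against at most 0.00763 in simulations of unchanged groups. Independent noise in the shared controls, as simulated, is therefore unlikely to account for it. A deviation common to both control arrays was not simulated. A batch shared by the nickel arrays and the hypoxia array on the second scale could also have raised the resemblance. As a partial check, the 2 h arrays were set beside the separately processed replicate 1 of hypoxia. Among probe sets changed at least 2-fold by both and by neither cobalt nor deferoxamine, 7 of 7 raised and 0 of 5 lowered lay above all 2 h arrays on it, a difference of 100 percentage points (95% interval 43.9 to 100). Among all probe sets changed at least 2-fold by both, 70 of 95 raised and 4 of 122 lowered did so, a difference of 70.4 points (95% interval 59.6 to 78.5). Most of the larger shared rises were thus also high on a hypoxia array of the other scale. The check cannot exclude a batch, since replicate 1 had no 24 h control on its scale and time in culture was not removed. Its background median was 22.4, against 5.7 to 14.8 on the 2 h arrays, and raised and lowered sets were not matched for level. Smaller changes were not covered.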

How the results depend on the processing

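The fit without nickel arrays, quantile normalization for lists and 5 comparisons between treatments were chosen after the data were seen, as was the use of the all-array model, first planned as the main fit, as an alternative. The limits of these results are few arrays, 1 hypoxia array at 24 h, and control signals that were not above background at 24 h for IGF2 and ENO2, which makes their fold sizes lower bounds set by the offset. Models of interactions of treatment with time and the comparison of controls between times, with their alternatives, were not run because the scales differ. Correlations of effects were recomputed only under quantile normalization, an offset of 64, no level filter and leave-one-out. Where no cause is named below, the cause was not tested.

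Counts at 24 h against controls stayed within 1.5 times of their values under every alternative within the scale except leave-one-out. Quantile normalization gave 25 probe sets for cobalt at 2 h. No level filter, with more probe sets tested, gave 234, 10 and 237 for hypoxia, cobalt and deferoxamine at 2 h, 43 for deferoxamine against hypoxia and 124 for cobalt against deferoxamine. A filter at the 60th percentile gave 32 for cobalt at 2 h and 153 for deferoxamine against hypoxia at 2 h. Variances without a trend gave 83, 4 and 68 for hypoxia, cobalt and deferoxamine at 2 h, 187, 23 and 48 for cobalt against hypoxia, deferoxamine against hypoxia and cobalt against deferoxamine at 2 h, and 126 for nickel against hypoxia. An offset of 64 moved no count by over 1.5 times. Without the nickel arrays the counts at 24 h were 2486 for hypoxia, 1937 for cobalt and 3775 for deferoxamine.

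With replicate number as a block, the counts were 234 for hypoxia and 215 (106 higher, 109 lower) for deferoxamine at 2 h. They were 46 for deferoxamine against hypoxia and 122 for cobalt against deferoxamine at 2 h. Nickel against hypoxia had 122 (59 higher, 63 lower), where the main fit had 127 higher and 104 lower. As a check of pairing, deviations of arrays with the same number correlated across probe sets at −0.130 to 0.0666 at 2 h and −0.0837 to 0.113 at 24 h. The cause of the lower counts was not tested.

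Leaving out 1 array at a time, which leaves a lone array assumed to vary like the other groups, gave 81 to 155 probe sets for hypoxia, 4 to 4 for cobalt and 46 to 107 for deferoxamine at 2 h. At 24 h it gave 1781 to 1835 for hypoxia, 1217 to 1455 for cobalt, 3140 to 3480 for deferoxamine and 2042 to 3083 for nickel. Between treatments at 2 h it gave 196 to 353 for cobalt against hypoxia, 17 to 63 for deferoxamine against hypoxia and 24 to 159 for cobalt against deferoxamine. At 24 h the same ranges were 2337 to 2376, 2335 to 2346 and 3067 to 3351, with 56 to 80 for nickel against hypoxia and 2376 to 3149 for nickel against cobalt. Of 41, 13 and 46 named genes called for hypoxia, cobalt and deferoxamine at 2 h, 8, 3 and 9 held in every such fit. At 24 h, 88 of 93, 83 of 91, 88 of 92 and 83 of 91 held for hypoxia, cobalt, deferoxamine and nickel.

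Correlations of effects ranged under leave-one-out from 0.220 to 0.538 for hypoxia and cobalt, 0.522 to 0.728 for hypoxia and deferoxamine and 0.275 to 0.640 for cobalt and deferoxamine at 2 h. At 24 h they ranged from 0.343 to 0.368 for hypoxia and cobalt, 0.613 to 0.633 for hypoxia and deferoxamine and 0.851 to 0.882 for hypoxia and nickel. The ranges were 0.508 to 0.531 for cobalt and deferoxamine, 0.427 to 0.461 for cobalt and nickel and 0.556 to 0.587 for deferoxamine and nickel. Here and in the leave-one-out counts above, the only hypoxia array of the 24 h fit was never left out. The ranges and calls held for hypoxia at 24 h therefore reflect only the other arrays. Quantile normalization gave 0.345 for hypoxia and cobalt, 0.612 for hypoxia and deferoxamine and 0.564 for deferoxamine and nickel at 24 h. An offset of 64 gave 0.633 for hypoxia and deferoxamine.

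Of 48 list shifts against controls, 11 were called with an estimated correlation, and fry called 80. The mean over probe sets gave 46, no level filter 50, the block 48 and quantile normalization 41. Fry tests against no change rather than against other genes. It called hepatocyte secreted proteins under cobalt at 24 h higher (adjusted p = 0.00923), where camera made no call (adjusted p = 0.901). Quantile normalization turned FTL under deferoxamine at 2 h from −0.17 to 0.25. The medians of called lists against controls kept their sign under it, although that of cytosolic ribosomal proteins under deferoxamine at 2 h went from −0.35 to −0.05, while cytosolic ribosomal proteins for cobalt against deferoxamine at 2 h did not.

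The all-array model gave 4 probe sets for hypoxia, 0 for cobalt and 0 for deferoxamine at 2 h, with 239, 144 and 222 at unadjusted p under 0.05 in limma. At 24 h it gave 1369 (67 higher, 1302 lower) for hypoxia, 61 (42 higher, 19 lower) for cobalt, 388 (210 higher, 178 lower) for deferoxamine and 34 for nickel. Against hypoxia it gave 1294 for cobalt, 724 for deferoxamine and 0 for nickel, with 2937 at unadjusted p under 0.05. By construction it averaged hypoxia arrays of both scales. It reversed 66 values of named genes, all in comparisons with hypoxia at 24 h and none past the test. Against control these were ALB −1.79, PGK1 −0.90, BNIP3 −0.0962, LDHA −0.73, TF −0.15, CP −0.32, TKT −0.98, APOA1 −0.16, F2 −0.23, APOC3 −0.23, ETFB −0.96, ECI1 −0.86, IDH2 −0.41, RPL19 −1.25, GDF15 −0.29, BAX −0.58, JUNB −0.46, IER3 −0.24, NFKBIA −1.13, CFB −0.098 and COL1A1 −1.15. For cobalt against hypoxia they were ALB 1.59, VEGFA 0.98, CDC20 0.11, MSMO1 0.0512, FDPS 1.18, ACAT2 0.98, ECI1 0.48, COX5A 0.90, NCL 0.86, BAX 0.39, TNFRSF10B 0.49, CCN2 0.58, IER3 0.0127, JUNB 0.46, CCL20 1.38, COL1A1 1.07 and LYZ 0.44. For deferoxamine against hypoxia they were ALB 1.73, SLC30A1 0.12, HMOX2 −0.0037, HSPD1 1.04, HSPE1 1.74, HSPB1 0.40, RBP4 0.13, F2 0.56, FDPS 1.18, ACAT2 0.96, MSMO1 0.31, HADH 0.91, NDUFV1 0.65, MYC 1.46, NOP16 1.00, NOP2 0.47, RPL14 0.94, RPL6 1.61, RPL19 1.33, RPS7 1.48, CCL20 1.46 and COL1A1 1.09. For nickel against hypoxia they were CXCL1 0.25, ADM 0.26, GDF15 0.38, JUNB 0.77, CCN2 1.49 and CCL20 1.23.

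Of 962 calls of named genes, 933 held under quantile normalization, 957 with an offset of 64, 884 without a level filter, 806 with variances without a trend and 891 with the block. Of 872 still tested at the 60th percentile, 872 held. Without the nickel arrays 531 of 536 held, and in the all-array model 209 of 671.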

Other observations

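The hypothesis on histone genes was formed after its first values were seen, and its test on other histone genes was chosen only then, while the prediction for the control replicates was written before.

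EPO, the hormone whose induction by low oxygen made Hep3B a common model, lay below the level filter in both fits. Its mean signal at 2 h was 11.1 ± 4.10 in controls, 9.55 ± 0.0707 under cobalt, 8.70 ± 0.707 under deferoxamine and 11.5 ± 5.23 under hypoxia (SD, n = 2). At 24 h it was 36.4 ± 0.283 in controls, 53.9 ± 8.98 under cobalt, 39.6 ± 3.18 under deferoxamine, 43.4 ± 5.30 under nickel and 70.7 on the hypoxia array (n = 1). HIF1A transcripts at 24 h were 7786 ± 631 in controls, 6615 ± 481 under cobalt, 5691 ± 320 under deferoxamine and 4926 ± 768 under nickel (SD, n = 2), and 6109 on the hypoxia array. Under deferoxamine the transcription factor JUND went from a log2 fold change of −0.96 ± 0.08 at 2 h to 1.76 ± 0.07 at 24 h, and CGA went from −0.68 ± 0.14 to 1.31 ± 0.10.

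Histone genes were noticed because H2AC15 (−1.90 ± 0.27), H2AC16 (−1.03 ± 0.10) and H2AC12 (−1.11 ± 0.30, adjusted p = 0.0669) were low after 2 h of deferoxamine. As a hypothesis, clustered histone genes fell together. The prediction was not met in the other 10 histone genes tested, since 0 were lower in limma. The 2 with an unadjusted p under 0.05, H2BC12 (0.42 ± 0.13) and H2BC5 (0.69 ± 0.28), were higher. The rest of the 10 stood below 0 without passing, from H2BC6 (−0.0056 ± 0.15) to H4C9 (−0.44 ± 0.48). With SE of this size the lack of calls cannot exclude a smaller joint fall. Variation between arrays could not be excluded as the source, since the median difference between the control replicates over the histone genes was −0.139 (log2). The call of H2AC15 ended without control replicate 2 (adjusted p = 0.0537). At 24 h of deferoxamine 5 of 10 histone genes were lower and 1 was higher, under cobalt 6 were lower and 0 higher, under nickel 2 were lower and 0 higher, and under hypoxia 2 were lower and 2 higher.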
